A study of Homo sapiens with 9 samples.

How the data were processed

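RNA sequencing of 9 libraries was analysed, 3 each of parental MV4;11 cells and of cells with the K148Q or K148R substitution in MYC. Per the labels, the cells were untreated and grown in RPMI medium, total RNA was extracted with the Zymo Quick-RNA Miniprep kit, and standard Illumina libraries were made. The series design speaks of mRNA profiles, but whether poly(A) selection was used is not given in the sources used here. Groups were taken from the genotype in the labels. The sample titles carry a code for each genotype (WT, Q2 and R14), whose meaning is not given in the sources used here.

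The authors deposited a table of raw read counts per gene symbol, with a column per library and no normalisation. The submitters' processing notes name FastQC 0.11.7, HISAT2 2.0.5, featureCounts 1.5.2 and the build GRCh38. The role and options of each tool, the strand of counting and the gene annotation are not given in the sources used here. The values were whole numbers whose totals differed between libraries, as raw counts do. The table held 26485 symbols, of which 8058 had 0 counts in all 9 libraries, and every one of its columns belonged to a sample of the series. Positions came from GENCODE v29 for 23899 symbols, from RefSeq for 751 and through a synonym for 754, and 1081 symbols had none. Symbols are printed as deposited, so some are older names, such as HIST1H1C and CECR1. Reads of near-identical genes, such as histones, HLA-DRB genes or ribosomal proteins and their pseudogenes, cannot be assigned with certainty from gene counts.

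Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group, which left 12845 genes, counts were scaled with TMM, and all 9 libraries were fitted together with a term per genotype. Contrasts were tested with the robust quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. No replicate term was used, because the replicate numbers name no shared batch. The common biological coefficient of variation was 0.074. Normalised values are CPM from edgeR on TMM-scaled library sizes. A permutation of 3 against 3 libraries cannot give a share below 0.1, so no exact test of a single gene could pass the threshold.

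Gene lists were tested with camera in limma 3.58.1 on voom-weighted log counts, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over all 96 tests. The lists covered MYC targets and partners, growth and metabolism, the cell cycle, cell death, blood lineages, immune responses and stress. They were written from textbook knowledge, some genes are on more than 1 list, and members found under an older symbol were matched through synonyms. Lists needed 5 tested members, so the T and NK cell markers, with 3, were not tested, and no mitochondrially encoded gene was in the table. Of 96 tests 43 were called, and 17 of these calls held with a correlation between genes estimated from the data. Each of the 43 calls given without its own estimated p in the text was among these 17. Calls that arose only in an alternative fit were not tested with an estimated correlation.

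The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named MYC first. For each comparison it then named the 8 genes with the largest rise and the 8 with the largest fall among changed genes with at least 10 CPM in the higher group and every library of that group above every library of the other, and the 4 genes with the smallest p in each direction. Genes without a proper symbol (LOC names), Y-linked genes, XIST, pseudogenes, and mitochondrial, ribosomal RNA and receptor segment genes were left out. From each list it named 4 members with the smallest p and up to 2 that did not pass, and from each class of shared genes the 5 with the largest smaller change. Some genes that the rule names are not reported here. Where a group had 0 counts, the bound on the fold was computed against 3 counts over the group. With 1 to 3 counts, the ratio of counts is given with its 95% interval.

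The overlap of calls was compared with that of independent lists and with 20 simulations in which all 3 groups were drawn from the parental means and both comparisons shared the simulated parental libraries. Each comparison was also tested on simulated data with 200 changed genes among 12845, 50 for each fold. At 1.25-fold, 26%, 38% and 28% of them were recovered for K148Q against parental, K148R against parental and K148R against K148Q, at 1.5-fold 70%, 80% and 86%, at 2-fold 90%, 90% and 86%, and at 4-fold 100% in each. False calls made up 8.9%, 5.5% and 5.1% of calls. In the data far more genes were called, 53.3%, 75.1% and 71% of those tested, so these shares do not carry over to them.

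Alternatives tried were DESeq2 1.42.0, limma-voom, other library scalings, other filters on low counts, a replicate term, fits of only the compared groups, a 2-fold threshold, other list tests, and leaving out each library in turn. A correction of counts for GC content and gene length was added after the data had been seen. The raw sequence reads and the protein were not analysed here.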

Results

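Gene expression was measured by RNA sequencing in MV4;11, a human acute myeloid leukaemia cell line with a rearranged MLL gene. There were 3 genotypes of MYC, the transcription factor that drives cell growth: parental cells, cells with the K148Q substitution and cells with the K148R substitution, with 3 libraries each. The substituted residue is a lysine in the parental protein. Glutamine, as in K148Q, is often used to mimic an acetylated lysine, and arginine, as in K148R, keeps the positive charge but cannot be acetylated. How the substitutions were introduced is not given in the sources used here. Total counts were 16502076, 13747087 and 16636974 in the parental libraries, 15116101, 14477839 and 15708821 in the K148Q libraries, and 18938391, 15161009 and 16440308 in the K148R libraries. Values below are normalised counts scaled to library size (CPM) as mean ± SD of n = 3 libraries, and positions are on GRCh38. A group with 0 counts in its 3 libraries lies below a floor of 3 counts over the group, which was 0.0636 CPM in parental, 0.0651 in K148Q and 0.0609 in K148R cells. Intervals and floors cover counting error only.

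The 3 genotypes separated from each other along the first principal component, with 71% of the variance, and the second, with 22.2%. Parental libraries differed little beyond counting error, with a chi-square per degree of freedom of 1.55 to 1.62 between pairs. K148R pairs ranged from 3.03 to 5.22. K148Q replicates 1 and 2 differed by 1.35, but K148Q replicate 3 stood apart from them, at 17.8 and 18.3. Its deviation followed the GC content of genes, with a Spearman correlation of -0.72 across genes, which are not independent replicates. The p-values below measure the spread between these libraries, and the labels do not say whether the libraries of a group came from separate cultures.

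MYC mRNA (chromosome 8, 127735434 to 127741434) was present in all 9 libraries and differed modestly between genotypes. It was 333 ± 4.05 CPM in parental cells, 473 ± 29.5 in K148Q cells and 379 ± 3.38 in K148R cells. Per library it was 335.4, 328.8 and 336.1 in parental, 488.6, 490.7 and 438.6 in K148Q, and 382.2, 378.7 and 375.4 in K148R cells. Its log2 fold change was 0.50 in K148Q against parental cells (adjusted p = 1.5e-06), 0.18 in K148R against parental cells (adjusted p = 0.0045) and -0.32 in K148R against K148Q cells (adjusted p = 5.2e-05), each with an SE of 0.051. Gene counts do not show the codon of that residue, so they do not check the substitution itself.

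**Figure D1:**
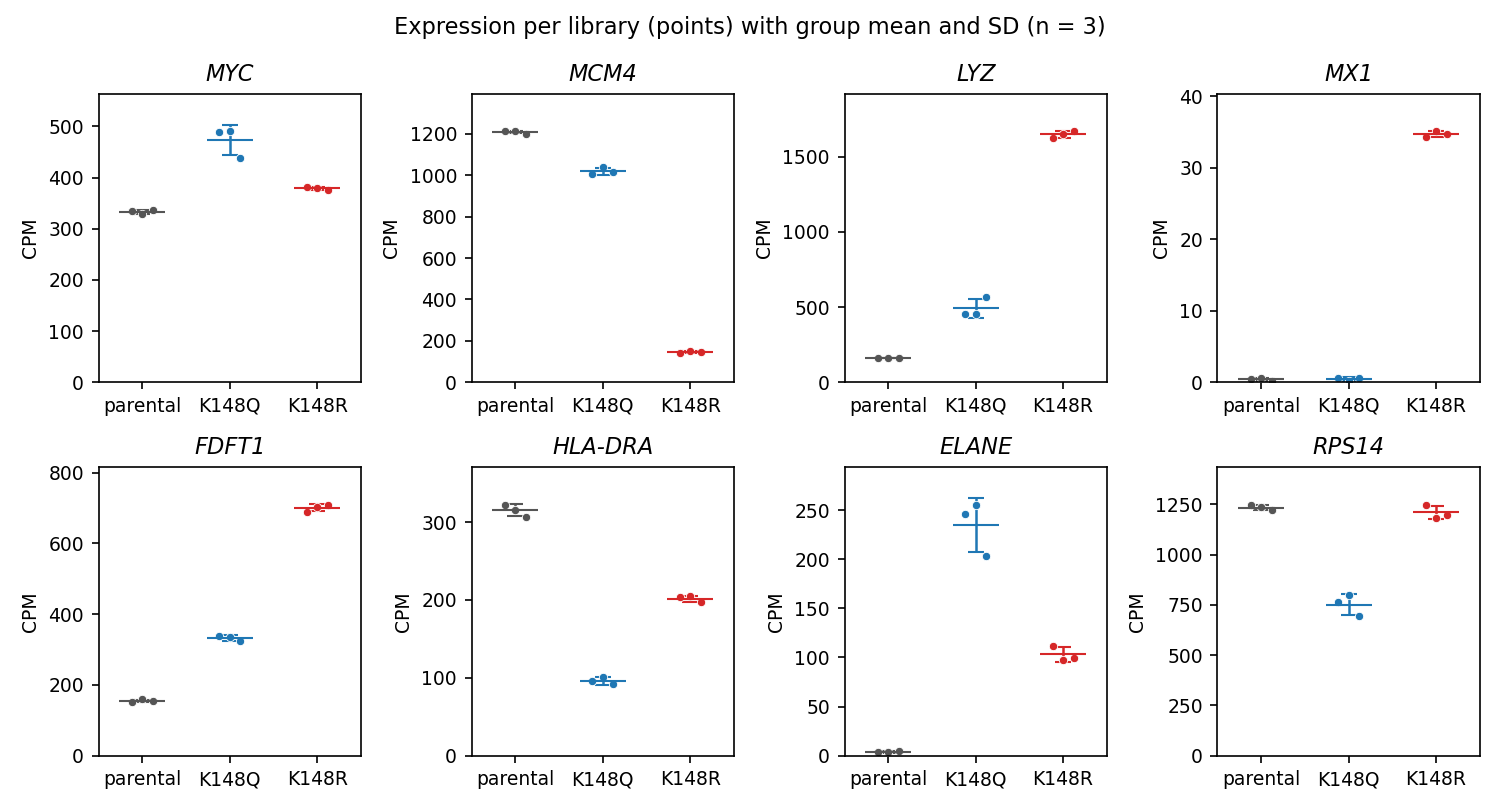
Normalised expression in CPM (y axes, from 0) of 8 genes in the 9 libraries, with points for libraries, long bars for group means and short bars for 1 SD (n = 3). MCM4 and MX1 separate K148R from both other genotypes, while RPS14 is lower in K148Q, at 751 CPM against 1230 in parental and 1210 in K148R cells.

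The first comparison asked how K148Q cells differed from parental cells. Of the cholesterol synthesis genes tested 19 of 23 rose, and all 11 genes of MHC class II antigen presentation fell. Granule and neutrophil markers rose in 10 of 15 cases (camera adjusted p = 0.15 with an estimated correlation). Of 74 cytosolic ribosomal protein genes, 72 fell (camera adjusted p = 0.18 with an estimated correlation). ELANE (chromosome 19, 851014 to 856247), which encodes neutrophil elastase, rose from 3.82 ± 0.622 to 235 ± 27.6 CPM. FDFT1, which makes squalene on the way to cholesterol, rose from 155 ± 3.31 to 332 ± 7.3 CPM. HLA-DRA, a chain of an MHC class II molecule, fell from 315 ± 7.62 to 96.2 ± 4.81 CPM. TEX19 (chromosome 17, 82359247 to 82363776), a gene known from germ cells, fell from 132 ± 1.47 to 0.346 ± 0.0867 CPM.

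Of 12845 tested genes, 6848 (53.3%) differed between K148Q and parental cells by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 3466 higher and 3382 lower. The median absolute log2 fold change over all tested genes was 0.3, and 1463 of the changed genes differed at least 2-fold, 605 higher and 858 lower. Among the genes with the largest rises, BEX1 (chromosome X, 103062651 to 103064240) went from 2.95 ± 0.332 to 243 ± 7.04 CPM, a log2 fold change of 6.37 (adjusted p = 3.8e-16). PPP1R3A, ADGRL3 and STON1 rose from under 1 CPM to 26.3 ± 6.61, 27.2 ± 3.1 and 17.5 ± 2.75 CPM. GATA2, a transcription factor of blood progenitors, rose from 1.43 ± 0.528 to 22.1 ± 1.67 CPM, and the chemokine gene CCL2 from 1.18 ± 0.128 to 15.3 ± 1.82 CPM. In the other direction, GLB1L2 (chromosome 11, 134331874 to 134378341) had 21.4 ± 1.38 CPM in parental cells and 0 counts in K148Q cells, at least 328-fold lower. AGK (chromosome 7, 141551189 to 141655244), a mitochondrial lipid kinase, had 14.2 ± 0.744 CPM in parental cells and 0 counts in K148Q cells, at least 217-fold lower. The log2 fold changes of CREB5, RET, KRT18, FAM69C and COL27A1 ran from -7.99 to -6.10. DTX4 fell from 199 ± 2.42 to 17.4 ± 1.41 CPM, MPEG1, which encodes a pore-forming protein of macrophages, from 145 ± 3.47 to 9.68 ± 0.923 CPM, and LSP1 from 303 ± 1.48 to 38.2 ± 4.03 CPM. The annotated ends of DTX4 and MPEG1 overlap, and the strand of counting is not given in the sources used here.

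Granule and neutrophil markers rose in K148Q cells, with 10 of 15 tested members higher and 2 lower (median log2 fold change 1.08, camera adjusted p = 5.2e-05, adjusted p = 0.15 with an estimated correlation). Besides ELANE, CTSG, which encodes cathepsin G, rose from 9.96 ± 0.274 to 138 ± 9.92 CPM, PRTN3, which encodes proteinase 3, from 178 ± 4.87 to 1090 ± 100 CPM, and MS4A3 from 58.5 ± 0.417 to 296 ± 21.6 CPM. CXCR2 did not pass the test (17.2 and 19.7 CPM). Of the cholesterol synthesis genes, 19 of 23 rose and 0 fell (median 1.04, camera adjusted p = 6.2e-10), among them LSS, which makes lanosterol, from 15.4 ± 0.606 to 47.9 ± 4.09 CPM. Lysosome and autophagy genes rose too, with 19 of 28 higher and 0 lower (median 0.40, camera adjusted p = 1.4e-06, adjusted p = 0.11 with an estimated correlation), among them the lysosomal proteases CTSA (104 to 236 CPM) and CTSD (219 to 473 CPM). Each of the counts in this paragraph was the same when adjusted over the list alone.

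All 11 tested MHC class II presentation genes fell in K148Q cells (median -1.62, camera adjusted p = 5.1e-08). CD74, the invariant chain, fell from 1130 ± 21.8 to 468 ± 47.8 CPM and HLA-DRB1, a close relative in sequence of HLA-DRB5, from 105 ± 2.45 to 34.3 ± 2.84 CPM. Of 74 cytosolic ribosomal protein genes, 72 fell and 0 rose, each by less than 2-fold (median -0.46, camera adjusted p = 1.1e-24, adjusted p = 0.18 with an estimated correlation). For this list K148Q replicate 3 deviated by a median of -0.16 from the other K148Q libraries, and without it the median was -0.39 (adjusted p = 6.6e-27). RPS3A fell from 2190 ± 34.2 to 1400 ± 43.9 CPM and RPL5 from 1960 ± 43.5 to 1230 ± 40.2 CPM, while RPS15 (787 and 719 CPM) and RPS26 (163 and 150 CPM) did not pass the test. Transcripts that host small nucleolar RNAs fell in 14 of 18 cases with 0 higher (median -0.37, camera adjusted p = 2.4e-05, adjusted p = 0.063 with an estimated correlation), such as SNHG1 (109 to 66.6 CPM) and GAS5 (146 to 97 CPM). Of 18 hypoxia response genes, 12 fell and 3 rose (median -0.61, camera adjusted p = 0.0032, adjusted p = 0.063 with an estimated correlation), with BNIP3 falling from 36.1 to 14.3 CPM and NDRG1 from 163 to 88.7 CPM. Adjusted over the list alone, 13 hypoxia genes fell and 3 rose, and the other counts in this paragraph were the same.

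A further pair of lists in K148Q cells passed the threshold only with K148Q replicate 3, the library that stood apart, while their medians moved little without it. Of 24 NF-kappaB and inflammatory genes, 16 were lower and 5 higher (median -0.50, camera adjusted p = 0.013, adjusted p = 0.34 with an estimated correlation, and median -0.44 with adjusted p = 0.056 without that replicate). TNFAIP3, an inhibitor of the pathway, fell from 44.0 ± 4.19 to 17.1 ± 0.636 CPM, while CCL2 and NFKB1 (38.1 to 74.6 CPM) rose. Of 35 type I interferon response genes, 15 were higher and 5 lower (median 0.32, or 0.2 with members near 0 counts held at their bounds, camera adjusted p = 0.037, adjusted p = 0.12 with an estimated correlation). This interferon call ended without K148Q replicate 3 (median 0.26, adjusted p = 0.083) and with the GC content and length correction (adjusted p = 0.071), although the corrected median was 0.35, with 17 higher and 5 lower. IFI6 rose from 3.49 ± 0.258 to 9.8 ± 1.12 CPM, whereas BST2 (214 and 231 CPM) did not pass the test. The counts of both lists were the same when adjusted over the list alone.

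MYC target and cell cycle lists gave no call in K148Q against parental cells. Of 54 MYC-activated growth genes, 13 rose and 15 fell (median -0.02, camera adjusted p = 0.55, and median 0.05 without K148Q replicate 3, so its sign turned with the library that stood apart). Among them FBL, NPM1 and HSPD1 fell, HSPD1 from 1610 ± 27.3 to 1120 ± 83.8 CPM, while NOP56 (376 and 399 CPM) did not pass. Of 23 genes held down by MYC, 8 rose and 9 fell (camera adjusted p = 0.79), a list whose median of 0.01 and mean of 0.08 were above 0 while the test's direction was down, and whose median was -0.04 without K148Q replicate 3. The MYC network list just missed the threshold, with 10 of 16 higher and 2 lower (median 0.21, camera adjusted p = 0.05), and was called in 4 of the 9 fits that left out a library (adjusted p from 0.04 to 0.065). DNA replication and G1/S genes had 6 of 40 higher and 12 lower (median -0.03, camera adjusted p = 0.47), and MCM4 fell by 0.25 on the log2 scale. Mitosis and G2/M genes had 13 of 40 higher and 9 lower (median 0.10, camera adjusted p = 0.43, and median 0.05 with adjusted p = 0.92 without K148Q replicate 3), with MKI67 rising from 512 to 772 CPM and TOP2A falling from 1020 to 670 CPM. Nucleotide and one-carbon synthesis genes had 5 of 30 higher and 13 lower (camera adjusted p = 0.18), and oxidative phosphorylation genes had 16 of 57 higher and 12 lower (camera adjusted p = 0.78). For p53 targets 4 of 28 were higher and 10 lower (camera adjusted p = 0.12, and 0.051 without K148Q replicate 3). For the BCL2 family 2 of 13 were higher and 6 lower (camera adjusted p = 0.07). The BCL2 family was called lower with the GC content and length correction (camera adjusted p = 0.05 after rounding). Adjusted over the list alone, 14 nucleotide genes fell and 5 rose, 13 oxidative phosphorylation genes rose and 10 fell, and the other counts in this paragraph were the same.

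Monocyte and macrophage markers also gave no call in K148Q cells, with 8 of 21 higher and 5 lower (median 0.2, or 0.11 with members near 0 counts held at their bounds and 0.36 with the GC content and length correction, camera adjusted p = 0.26), although LYZ, which encodes lysozyme, rose from 161 ± 2.88 to 491 ± 64.5 CPM and CD68 from 175 to 312 CPM. Immediate early genes had 10 of 27 higher and 7 lower (camera adjusted p = 0.6), immune checkpoint and phagocytosis signals 5 of 16 higher and 4 lower (camera adjusted p = 0.48), and MHC class I presentation genes 6 of 15 higher and 4 lower (camera adjusted p = 0.31). Replication-dependent histones had 2 of 20 higher and 2 lower (camera adjusted p = 0.92). Adjusted over the list alone, 7 MHC class I genes rose and 4 fell, 1 histone gene rose and 1 fell, and the other counts in this paragraph were the same.

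The second comparison asked how K148R cells differed from parental cells. Genes of DNA replication and mitosis fell, while markers of monocytes, interferon response genes, cholesterol synthesis genes and most tested replication-dependent histones rose. MCM4 (chromosome 8, 47960185 to 47978160), a subunit of the replicative helicase, fell from 1210 ± 6.79 to 146 ± 2.96 CPM. LYZ rose from 161 ± 2.88 to 1650 ± 21.5 CPM, and MX1, an antiviral gene induced by interferon, from 0.393 ± 0.202 to 34.7 ± 0.385 CPM. FDFT1 rose from 155 ± 3.31 to 700 ± 10.3 CPM. The small nuclear RNA RN7SK, which has no poly(A) tail and was singled out after its values were seen, was at 522.6, 496.2 and 434.6 CPM in the K148R libraries, 6.5, 16 and 4.2 CPM in the parental libraries, and 7.4, 4.5 and 3.7 CPM in the K148Q libraries.

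Between K148R and parental cells 9649 of 12845 genes (75.1%) differed by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 4859 higher and 4790 lower. The median absolute log2 fold change was 0.58, and 3749 changed genes differed at least 2-fold, 1853 higher and 1896 lower. S100A8 (chromosome 1, 153390032 to 153391188), a calcium-binding protein abundant in monocytes and neutrophils, had 1 count in parental cells and 70.6 ± 1.0 CPM in K148R cells, a count ratio of 3330 (95% interval 597 to 131000). Its partner S100A9 rose from 0.144 ± 0.0621 to 51.8 ± 2.37 CPM. SIGLEC1, a macrophage receptor, had 2 counts in parental cells and 45.3 ± 1.68 CPM in K148R cells, a ratio of 1070 (296 to 8840), and ADAM28 had 1 count against 41.1 ± 2.1 CPM, a ratio of 1940 (347 to 76500). SDK2 went from 0 counts to 12.2 ± 1.02 CPM, at least 193-fold higher. CECR1, which encodes a secreted adenosine deaminase, rose from 20.7 ± 0.996 to 351 ± 10.2 CPM (log2 fold change 4.09, adjusted p = 1.1e-15). GTSF1 (chromosome 12, 54455950 to 54473602) had 59.5 ± 2.33 CPM in parental cells and 0 counts in K148R cells, at least 977-fold lower. ZNF486 had 30.7 ± 0.834 CPM in parental cells and TERT, the catalytic subunit of telomerase, 15.4 ± 0.373 CPM, and both had 0 counts in K148R cells, at least 505-fold and 253-fold lower. CD38 had 15.9 ± 1.39 CPM in parental cells and 1 count in K148R cells, a ratio of 786 (141 to 31100). SYT2 fell from 107 ± 1.28 to 0.189 ± 0.0812 CPM, and MRFAP1L1 from 49.5 ± 1.98 to 0.102 ± 0.0373 CPM.

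All 40 DNA replication and G1/S genes fell at least 2-fold in K148R cells (median -3.18, camera adjusted p = 1.7e-21). MCM6 fell from 647 ± 4.64 to 49.1 ± 3.18 CPM and MCM10 from 130 ± 5.15 to 3.93 ± 0.363 CPM. All 40 mitosis and G2/M genes fell as well (median -2.64, camera adjusted p = 8.1e-19), including TOP2A, which encodes a topoisomerase of dividing cells, from 1020 ± 19.6 to 123 ± 7.9 CPM and the spindle checkpoint gene BUB1B from 190 ± 5.45 to 15.6 ± 1.76 CPM. Nucleotide and one-carbon synthesis genes fell in 27 of 30 cases with 1 higher (median -1.22, camera adjusted p = 4.2e-10). RRM1, a subunit of ribonucleotide reductase, fell from 419 ± 4.65 to 48.5 ± 2.57 CPM, and TYMS, which encodes thymidylate synthase and is also on the replication list, from 376 ± 6.64 to 40 ± 2.29 CPM. Of 20 tested replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 19 rose and 1 fell (median 3.20, camera adjusted p = 7.4e-05). Only these 20 of 37 list members in the count table passed the filter on low counts. Most were under 1 CPM in parental and K148Q cells. Many thus passed only through the K148R libraries, which leans the count, median and call towards a rise. HIST1H1C rose from 3.38 ± 0.214 to 30.7 ± 1.18 CPM and HIST2H2BE from 0.352 ± 0.117 to 20.8 ± 2.97 CPM, alongside the RN7SK levels given above. Adjusted over the list alone, 27 nucleotide genes fell and 2 rose, and the other counts in this paragraph were the same.

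Of 54 MYC-activated growth genes, 41 were lower and 5 higher in K148R than in parental cells (median -0.44, camera adjusted p = 1.3e-05, adjusted p = 0.18 with an estimated correlation). HSPD1, a mitochondrial chaperonin, fell from 1610 ± 27.3 to 660 ± 27.1 CPM, TCOF1, which acts in ribosome biogenesis, from 229 ± 4.89 to 70.9 ± 6.66 CPM, and CAD, which starts pyrimidine synthesis, from 255 ± 2.47 to 104 ± 5.33 CPM. TMEM97, which acts in cholesterol handling, rose from 79.2 ± 2.8 to 233 ± 14.9 CPM. Genes held down by MYC rose in 16 of 23 cases with 5 lower (median 1.03, camera adjusted p = 0.01, adjusted p = 0.093 with an estimated correlation), among them the cell cycle inhibitor CDKN1A (102 to 371 CPM) and BTG2 (29.6 to 158 CPM), while CCND1, which encodes cyclin D1, fell from 25 to 1.49 CPM. The MYC network list just missed the threshold, with 10 of 16 higher and 2 lower (median 0.42, camera adjusted p = 0.05), and was called in 7 of the 9 fits that left out a library (adjusted p from 0.037 to 0.061). Its members MXD1 (10.2 to 60.5 CPM) and MXD4 (41.9 to 114 CPM), which compete with MYC for its partner MAX, rose, and so did MAX itself (80.8 to 141 CPM). Oxidative phosphorylation genes were lower in 33 of 57 cases and higher in 2 (median -0.23, camera adjusted p = 0.0012, adjusted p = 0.39 with an estimated correlation), and p53 targets were higher in 16 of 28 and lower in 3 (median 0.53, camera adjusted p = 0.023, adjusted p = 0.11 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 35 of 74 and higher in 13 (median -0.11, camera adjusted p = 0.022, adjusted p = 0.75 with an estimated correlation), a call that ended with the GC content and length correction (adjusted p = 0.17), which left 34 lower and 17 higher and a median of -0.07. The counts in this paragraph were the same when adjusted over the list alone.

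Monocyte and macrophage markers rose in 19 of 21 cases with 2 lower in K148R cells (median 2.42, camera adjusted p = 5.4e-07), including CX3CR1, a chemokine receptor of monocytes, from 3.68 ± 0.316 to 87.0 ± 0.531 CPM. Only 21 of the 30 list members in the count table passed the filter on low counts. Of these, 3 were at the floor in both parental and K148Q cells. They passed only through the K148R libraries, which leans the count and median towards a rise. Type I interferon response genes rose in 34 of 35 cases with 0 lower (median 2.68, camera adjusted p = 1.1e-10). IFI6 rose from 3.49 ± 0.258 to 104 ± 5.72 CPM and STAT2, a transducer of the interferon signal, from 50.7 ± 4.31 to 223 ± 4.04 CPM, while USP18 (3.75 and 4.36 CPM) did not pass the test. Cholesterol synthesis genes rose in 20 of 23 cases with 1 lower (median 2.22, camera adjusted p = 3.1e-08). LSS rose from 15.4 ± 0.606 to 185 ± 7.99 CPM, while FDPS (177 and 175 CPM) did not pass. Granule and neutrophil markers rose in 12 of 15 cases with 1 lower (median 0.95, camera adjusted p = 0.00058, adjusted p = 0.18 with an estimated correlation), with CTSG going from 9.96 ± 0.274 to 342 ± 14.6 CPM and ELANE from 3.82 ± 0.622 to 103 ± 7.57 CPM. Lysosome and autophagy genes rose in 26 of 28 cases with 1 lower (median 1.03, camera adjusted p = 6.6e-08, adjusted p = 0.083 with an estimated correlation), with SQSTM1, an autophagy receptor, going from 135 to 464 CPM. When each count was adjusted over the list alone, 20 cholesterol genes rose and 2 fell, and the other counts in this paragraph were the same.

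Immune checkpoint and phagocytosis signals rose in 13 of 16 cases with 2 lower in K148R cells (median 0.89, camera adjusted p = 0.0033, adjusted p = 0.34 with an estimated correlation), among them the costimulatory ligand CD86, from 0.443 ± 0.267 to 26.9 ± 1.9 CPM. NF-kappaB and inflammatory genes were higher in 16 of 24 cases and lower in 5 (median 0.53, camera adjusted p = 0.019, adjusted p = 0.35 with an estimated correlation). The cytokine genes IL1B (1.37 to 27.3 CPM) and CXCL8 (5.44 to 67.0 CPM) rose. Immediate early genes were higher in 19 of 27 cases and lower in 6 (median 0.93, camera adjusted p = 0.01, adjusted p = 0.19 with an estimated correlation), with JUN going from 1.06 ± 0.0316 to 52.5 ± 1.62 CPM. The GC content and length correction ended the calls for the NF-kappaB list (adjusted p = 0.071) and the immediate early list (adjusted p = 0.058). Both stayed on the same side of 0, with corrected medians of 0.34 (16 higher, 6 lower) and 0.74 (18 higher, 8 lower). No call was made in K148R against parental cells for MHC class II presentation, with 2 of 11 higher and 6 lower (camera adjusted p = 0.21), MHC class I presentation, with 9 of 15 higher and 5 lower (camera adjusted p = 0.24), hypoxia response, with 8 of 18 higher and 9 lower (camera adjusted p = 0.66), snoRNA host transcripts, with 4 of 18 higher and 9 lower (camera adjusted p = 0.33), or the BCL2 family, with 7 of 13 higher and 4 lower (camera adjusted p = 0.55). The counts in this paragraph were the same when adjusted over the list alone.

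The third comparison set the substitutions against each other, and is also the test of whether their differences from parental cells differ. Relative to K148Q cells, K148R cells had less mRNA of all 40 replication and 39 of 40 mitosis genes and more of 20 of 21 monocyte markers and 31 of 35 interferon response genes. MCM10, which acts in starting replication, was at 132 ± 3.16 CPM in K148Q and 3.93 ± 0.363 CPM in K148R cells. CECR1 was at 9.1 ± 0.302 CPM in K148Q and 351 ± 10.2 CPM in K148R cells, and LSP1 at 38.2 ± 4.03 and 695 ± 36.0 CPM. CD74 was at 468 ± 47.8 CPM in K148Q and 1070 ± 30.9 CPM in K148R cells.

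Between K148R and K148Q cells 9126 of 12845 genes (71%) differed by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 4698 higher and 4428 lower in K148R. The median absolute log2 fold change was 0.51, and 3327 changed genes differed at least 2-fold, 1768 higher and 1559 lower. CD59 (chromosome 11, 33703010 to 33736491), which shields cells from complement, had 1 count in K148Q and 126 ± 8.06 CPM in K148R cells, a ratio of 5790 (95% interval 1040 to 229000). ADAM28 had 0 counts in K148Q cells and was at least 630-fold higher in K148R cells. GLB1L2 and CSMD3 had 0 counts in K148Q cells and were at least 232-fold and 230-fold higher in K148R cells, both at 15 CPM. AGK, also at 0 counts in K148Q cells, was at 10.3 ± 0.879 CPM in K148R cells, at least 159-fold higher. FCGR2B, an Fc receptor with close relatives, had 2 counts in K148Q and 24.3 ± 1.14 CPM in K148R cells, a ratio of 561 (155 to 4640). DTX4 was at 17.4 ± 1.41 and 357 ± 4.08 CPM (log2 fold change 4.36, adjusted p = 1.6e-15). In the other direction, GTSF1 and NDN had 52.6 ± 1.73 and 21.3 ± 0.601 CPM in K148Q and 0 counts in K148R cells, at least 863-fold and 350-fold lower. SLC46A1, a folate transporter, had 11.5 ± 1.56 CPM in K148Q and 1 count in K148R cells, a ratio of 563 (101 to 22300). FKBP9 and GIPC3 had log2 fold changes of -7.05 and -6.92.

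All 40 DNA replication and G1/S genes were lower in K148R than in K148Q cells (median -3.02, camera adjusted p = 6.5e-24), and so were 39 of 40 mitosis and G2/M genes (median -2.81, camera adjusted p = 1.3e-20), with BUB3 (329 and 339 CPM) not passing. Nucleotide and one-carbon synthesis genes were lower in 27 of 30 cases and higher in 1 (median -1.05, camera adjusted p = 1.1e-10), with RRM2 at 358 ± 20.4 in K148Q and 34.3 ± 2.65 CPM in K148R cells. MYC-activated growth genes were lower in 39 of 54 and higher in 4 (median -0.35, camera adjusted p = 7.4e-06, adjusted p = 0.17 with an estimated correlation), with CAD at 333 ± 31.7 and 104 ± 5.33 CPM and NPM1 (1240 and 1190 CPM) not passing. Genes held down by MYC were higher in 16 of 23 and lower in 6 (median 0.93, camera adjusted p = 0.01, adjusted p = 0.093 with an estimated correlation). Oxidative phosphorylation genes were lower in 42 of 57 and higher in 4 (median -0.25, camera adjusted p = 0.00011, adjusted p = 0.32 with an estimated correlation). The p53 targets were higher in 23 of 28 and lower in 2 (median 0.79, camera adjusted p = 0.00014), with CDKN1A at 110 ± 10.3 in K148Q and 371 ± 16.7 CPM in K148R cells. Cytosolic ribosomal protein genes were higher in 61 of 74 and lower in 0 (median 0.31, camera adjusted p = 2.1e-09, adjusted p = 0.41 with an estimated correlation), as in RPS14, at 751 ± 53.5 and 1210 ± 34.2 CPM. When each count was adjusted over the list alone, 40 MYC-activated growth genes were lower and 4 higher, 17 genes held down by MYC were higher and 6 lower, 43 oxidative phosphorylation genes were lower and 4 higher, and the other counts in this paragraph were the same.

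Monocyte and macrophage markers were higher in K148R than in K148Q cells in 20 of 21 cases and lower in 1 (median 1.75, camera adjusted p = 2.9e-08). The same 3 markers passed the filter only through the K148R libraries. Interferon response genes were higher in 31 of 35 and lower in 0 (median 2.49, camera adjusted p = 1.7e-09). OAS2 was at 3.22 ± 0.43 in K148Q and 49.8 ± 3.05 CPM in K148R cells. Replication-dependent histones were higher in 19 of 20 and lower in 0 (median 2.95, camera adjusted p = 1.6e-05), with HIST1H2AC at 0.779 ± 0.0789 and 16.1 ± 1.76 CPM, alongside RN7SK with a log2 fold change of 6.54. This histone result has the same limit as against parental cells, since many of the 20 genes passed the filter only through the K148R libraries. Cholesterol synthesis genes were higher in 18 of 23 and lower in 3 (median 1.08, camera adjusted p = 2.4e-05), as in HMGCS1, at 64.4 ± 6.72 and 303 ± 22.2 CPM. MHC class II genes were higher in 9 of 11 and lower in 1 (median 1.07, camera adjusted p = 0.0032, adjusted p = 0.074 with an estimated correlation), with CIITA, their master regulator, at 11.9 ± 1.4 in K148Q and 42.7 ± 5.55 CPM in K148R cells. NF-kappaB and inflammatory genes were higher in 20 of 24 and lower in 2 (median 1.35, camera adjusted p = 2e-05, adjusted p = 0.14 with an estimated correlation), with PLAUR at 41.9 ± 3.13 and 150 ± 3.6 CPM. Lysosome and autophagy genes were higher in 24 of 28 and lower in 3 (median 0.62, camera adjusted p = 4.7e-05, adjusted p = 0.16 with an estimated correlation). When each count was adjusted over the list alone, 31 interferon genes were higher and 1 lower, and the other counts in this paragraph were the same.

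The immediate early and checkpoint calls between K148R and K148Q cells did not hold in every alternative. Immediate early genes were higher in 14 of 27 and lower in 4 (median 0.25, camera adjusted p = 0.033, adjusted p = 0.28 with an estimated correlation, and adjusted p = 0.095 with the GC content and length correction, where the median was 0.08, with 13 higher and 6 lower). Immune checkpoint and phagocytosis signals were higher in 11 of 16 and lower in 3 (median 0.72, camera adjusted p = 0.047, adjusted p = 0.52 with an estimated correlation). That call ended without K148Q replicate 3 (median 0.65, adjusted p = 0.051) and with the GC content and length correction (adjusted p = 0.071), where the median was 0.52, with 10 higher and 4 lower. Granule and neutrophil markers gave no call, with 6 of 15 higher and 8 lower (camera adjusted p = 0.81): CTSG was higher in K148R, PRTN3 was lower, at 1090 ± 100 in K148Q and 294 ± 11.1 CPM in K148R cells, and the list's median of -0.13 and mean of 0.33 differed in sign. MHC class I genes gave no call either, with 6 of 15 higher and 7 lower (camera adjusted p = 0.9), a median of -0.10 against a mean of 0.04 and a test direction of up. The MYC network (9 of 16 higher, 5 lower, camera adjusted p = 0.38), the BCL2 family (8 of 13 higher, 3 lower, camera adjusted p = 0.22), hypoxia response (8 of 18 higher, 4 lower, camera adjusted p = 0.35) and snoRNA host transcripts (8 of 18 higher, 6 lower, camera adjusted p = 0.39) did not pass. When each count was adjusted over the list alone, 7 granule and neutrophil markers were higher and 8 lower. The other counts in this paragraph were the same.

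**Figure D2:**
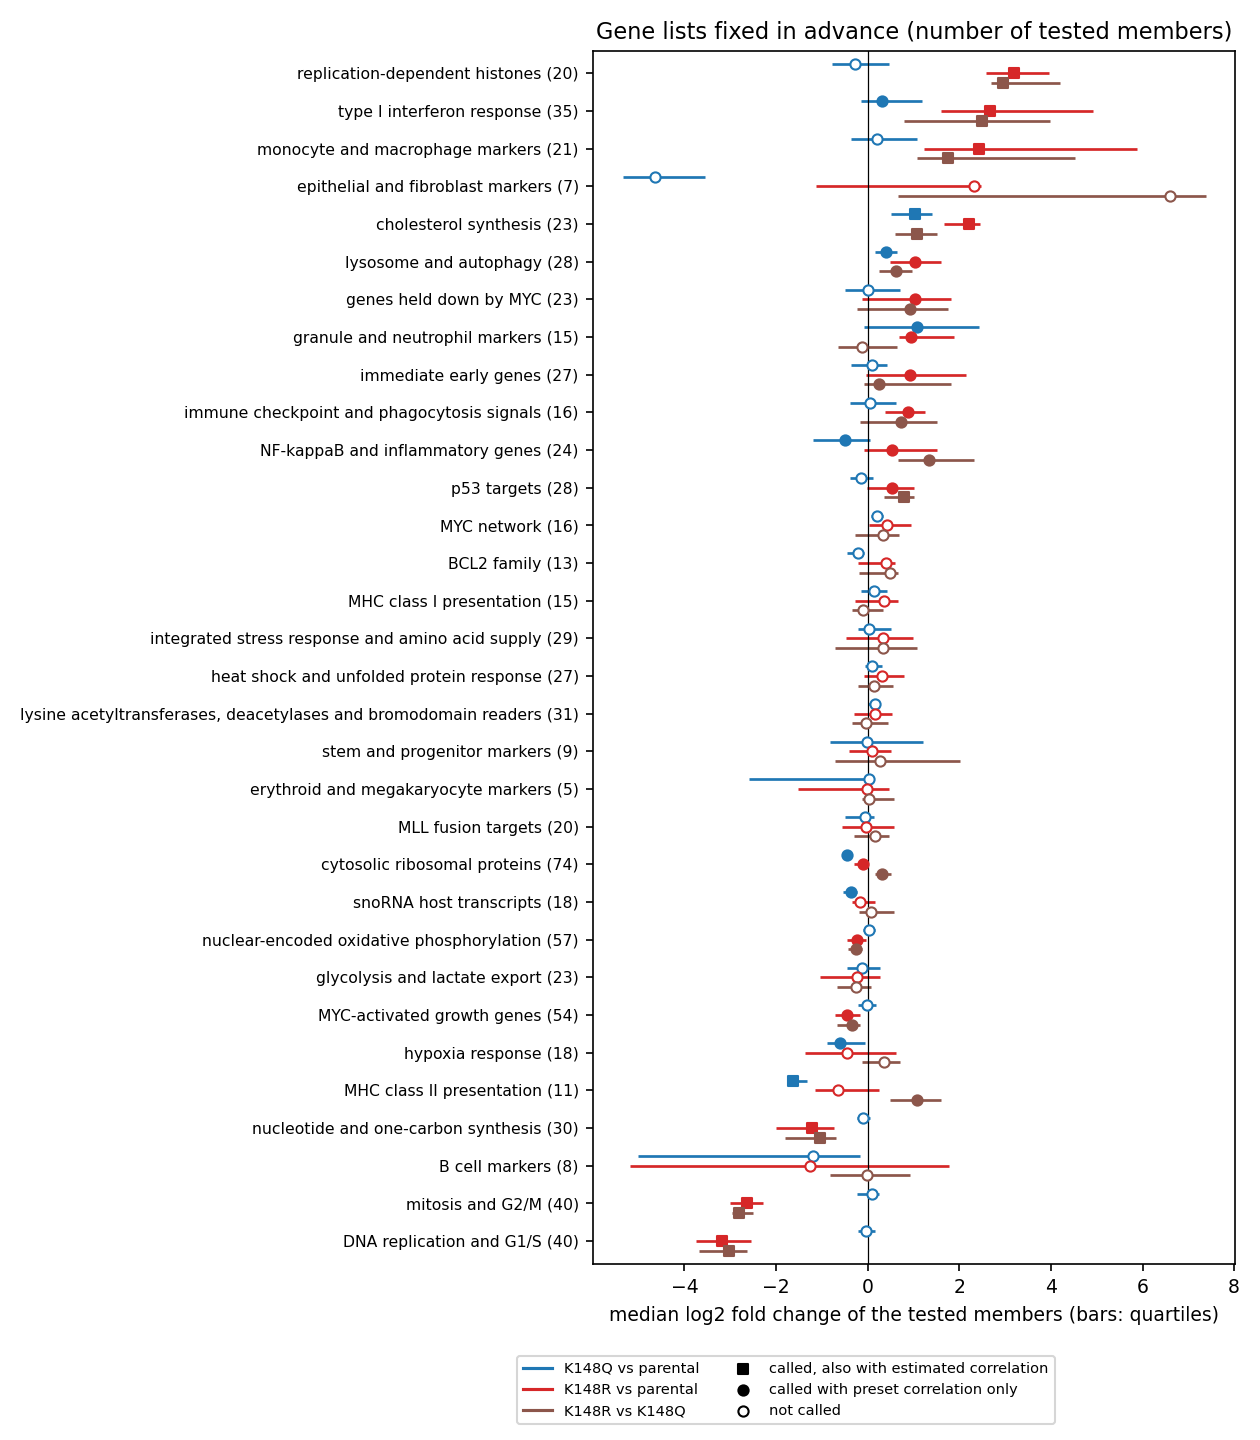
Median log2 fold change of the tested members of each gene list (x axis, bars from the lower to the upper quartile), for K148Q against parental, K148R against parental and K148R against K148Q cells, with marker shape for the camera call. The DNA replication list sits at -3.18 and -3.02 in the K148R comparisons and at -0.03 in K148Q against parental cells, and fitted values of members with 0 counts in a group enter the medians.

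The last comparison asked which genes differed in both substitution groups from the same parental libraries. With 1 title code per substitution, such differences cannot be told apart from divergence of the cells apart from the substitution. Both groups had more BEX1, ELANE, CTSG, CCL2 and IGF1 and less TEX19, KRT18, CREB5, RET and FAM69C than parental cells. BEX1 reached 243 ± 7.04 CPM in K148Q and 245 ± 1.01 CPM in K148R cells, from 2.95 ± 0.332 CPM in parental cells. IGF1, which encodes a growth factor, went from 2.28 ± 0.241 to 27.3 ± 5.01 CPM in K148Q and 277 ± 7.84 CPM in K148R cells. TEX19 fell to 0.346 ± 0.0867 and 1.37 ± 0.0995 CPM.

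By edgeR quasi-likelihood, 2231 genes were higher in both groups, where independent lists would share 1311, and 2032 were lower in both, where independent lists would share 1261. Of the genes changed in both, 4263 (77.2%) moved the same way. A further 613 genes were higher in K148Q and lower in K148R cells, where independent lists would share 1292, and 645 were lower in K148Q and higher in K148R cells, where they would share 1279. With a 2-fold change required in both, 379 genes were higher in both (87.3 for independent lists), 400 lower in both (126.6), 38 higher in K148Q and lower in K148R (89.3), and 122 lower in K148Q and higher in K148R (123.8). Genes that moved apart included ITGA6, an integrin chain, at 10.8 ± 0.34 CPM in parental, 32.2 ± 3.96 in K148Q and 1.28 ± 0.266 in K148R cells, and PYGL, the liver glycogen phosphorylase, at 301 ± 2.83, 589 ± 11.1 and 145 ± 6.14 CPM. In the opposite order, AMICA1, an adhesion molecule of leukocytes, was at 11.5 ± 0.477, 1.82 ± 0.227 and 117 ± 1.71 CPM, and TCF4, a transcription factor of dendritic cells, at 19.8 ± 0.965, 4.05 ± 0.381 and 85.2 ± 2.88 CPM. The log2 fold changes of the 2 comparisons had a covariance of 0.509 across genes, which are not independent replicates. In 20 simulations of 3 unchanged groups, with the parental libraries simulated too and shared by both comparisons, the mean covariance was 0.0275 and the highest 0.0333, and 0 genes were called in both comparisons. With no gene changed, a count near 0 was set by the design and gives no reference for the 4263 shared genes. The correlation was 0.35, against a mean of 0.5 in the simulations, where shared parental noise alone sets it, so it does not measure a shared change. The 3 parental libraries were not divided between the comparisons, so the excess over independent lists includes any part that comes from sharing them.

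**Figure D3:**
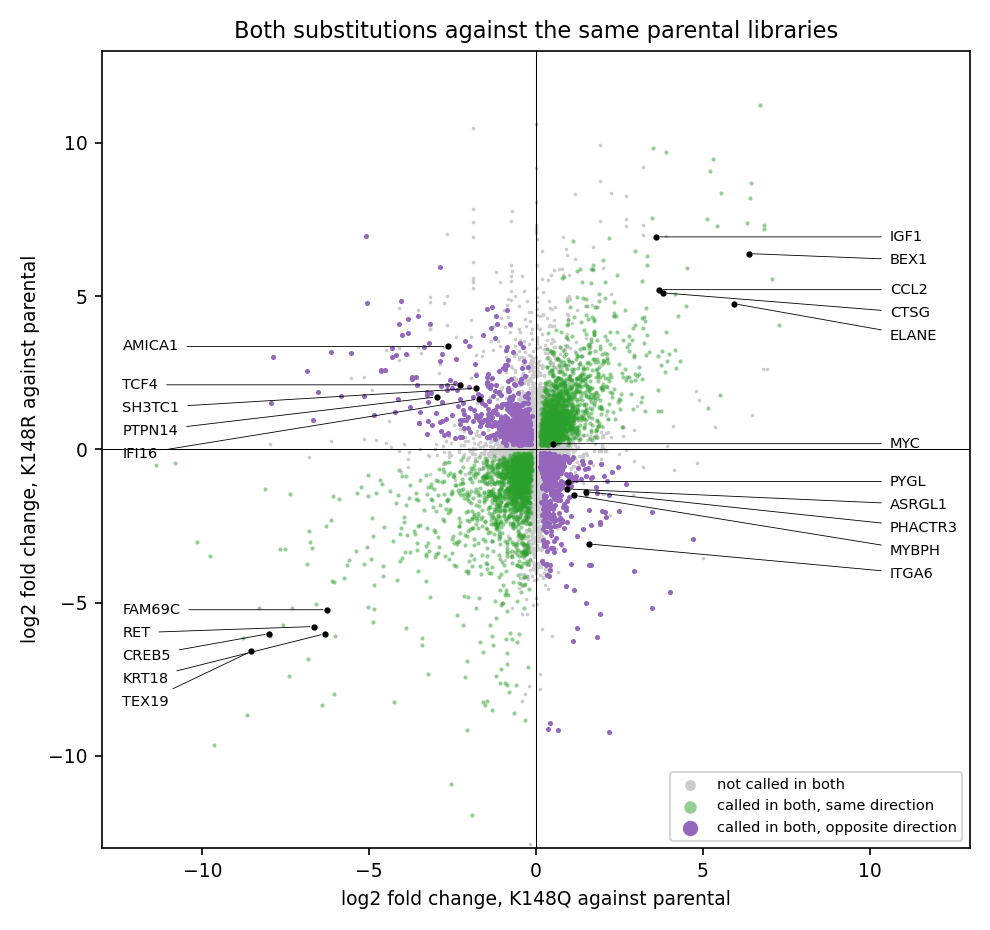
Log2 fold change against parental cells of each tested gene in K148Q (x axis) and K148R cells (y axis), fitted values with a prior count. The covariance across genes is 0.509, and 4263 genes changed in the same direction in both comparisons against 1258 in opposite directions.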

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

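The gene-wise tests in this part were fixed in advance, and the GC content and length correction was chosen only after the results were seen. A result is listed here because its difference from parental cells was in opposite directions in K148Q and K148R cells, and the direct test of K148R against K148Q also passed. The values are log2 fold changes of K148R minus K148Q, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment.

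In 5 genes K148Q was above and K148R below parental cells. ITGA6 differed by -4.66 (adjusted p = 1.6e-12), PHACTR3 by -2.88 (adjusted p = 3.1e-13), MYBPH by -2.65 (adjusted p = 4.3e-13), PYGL by -2.02 (adjusted p = 7.3e-14) and ASRGL1 by -2.23 (adjusted p = 2.1e-11). In 5 genes the order was the opposite. AMICA1 differed by 6 (adjusted p = 3.2e-15), TCF4 by 4.39 (adjusted p = 3e-14), SH3TC1 by 3.78 (adjusted p = 5.7e-13), PTPN14 by 4.68 (adjusted p = 3.8e-14) and IFI16, a sensor of DNA, by 3.36 (adjusted p = 3.2e-13). These 10 genes were picked for the largest opposed changes, so the direct test passes largely by that choice and is no separate evidence.

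The NF-kappaB and inflammatory genes had a median difference of 1.35 between K148R and K148Q cells (camera adjusted p = 2e-05, adjusted p = 0.14 with an estimated correlation). Their call against parental cells ended in K148Q without K148Q replicate 3 (adjusted p = 0.056), where the median went from -0.50 to -0.44, and in K148R with the GC content and length correction (adjusted p = 0.071), which took the median there from 0.53 to 0.34, with 16 higher and 6 lower.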

How the results depend on the processing

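Tests of the GC content and length correction were chosen only after the results were seen, and every other alternative was fixed in advance. With a 2-fold change required, the counts of changed genes went to 1463 for K148Q against parental, 3749 for K148R against parental and 3327 for K148R against K148Q cells, and the genes shared in the same direction to 779, since the threshold is stricter. List calls went from 43 to 17 with an estimated correlation and to 81 with fry, which does not compare a list with other genes. Leaving out a library gave 5829 to 8402, 9164 to 10473 and 8675 to 9736 changed genes, 3597 to 5317 shared genes and 43 to 46 list calls, with the highest gene counts without K148Q replicate 3. Under DESeq2, limma-voom, other scalings and filters, fits of only the compared groups and the GC content and length correction, the counts of changed genes stayed within 1.5 times the reported ones, from 6460 to 7787, 9339 to 10213 and 8506 to 9717. Shared genes ran from 4026 to 4330 where an alternative gave them. Without K148Q replicate 3, 40 of the 43 reported list calls were kept, 50 values of named genes newly passed and 2 no longer did. The correction gave 39 list calls, 37 of them among the reported ones. It added the BCL2 family in K148Q against parental cells (camera adjusted p = 0.05) and heat shock genes in K148R against parental cells (camera adjusted p = 0.047). Scaling by library totals put 53.3%, 47.7% and 46.9% of changed genes higher, against 50.6%, 50.4% and 51.5%, and the correction put 57%, 50.6% and 48.3% higher. A replicate term gave 7262, 9821, 9410 and 4567 genes and 45 list calls. Deviations of libraries with the same number correlated by at most 0.27 (Pearson r across genes), in replicate 3 of K148Q and K148R. For libraries of different genotypes and different numbers the range was -0.24 to 0.17. Of 611 values of named genes, PSMB10 in K148R against K148Q cells changed sign without K148Q replicate 3, from 0.02 to -0.13 (adjusted p = 0.021), and was 0.09 without K148Q replicate 2. The cause was not tested. Depth limits genes near the floors, where a group with 0 counts gives a bound and not a fold.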

Other observations

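Tests of the GC content and length correction and of the number of title codes were chosen only after the results were seen. Several lists gave no call in any comparison while single members moved far. Among stem and progenitor markers, with 9 tested, SOX4 was at 83.8 CPM in parental, 20.8 in K148Q and 84.6 in K148R cells, and KIT, the stem cell factor receptor, at 32.1, 74.4 and 17.4 CPM, with 3 members higher and 3 lower in K148Q and 4 higher and 3 lower in K148R cells against parental cells (camera adjusted p = 0.93 and 0.92, and 0.93 between the substitutions, 5 higher and 4 lower). Among 20 MLL fusion targets, FLT3 fell from 652 to 301 CPM in K148R cells and MEF2C from 161 to 64.5 in K148Q and 37.2 in K148R cells, with 4 higher and 7 lower, 9 higher and 9 lower, and 10 higher and 7 lower in the 3 comparisons (camera adjusted p = 0.22, 0.85 and 0.65). In K148Q against parental cells the MLL list had a median of -0.18 without K148Q replicate 3 (camera adjusted p = 0.051). With the GC content and length correction that median was 0.03. Of 31 lysine acetyltransferases, deacetylases and bromodomain readers, 14 were higher and 4 lower in K148Q, 15 higher and 10 lower in K148R, and 12 higher and 12 lower between them (camera adjusted p = 0.12, 0.48 and 0.99), and CREBBP, an acetyltransferase, was at 45.1, 68.5 and 147 CPM. Without K148Q replicate 3 this list was called higher in K148Q against parental cells (camera adjusted p = 0.032). With the GC content and length correction, 13 of its members were higher and 15 lower in K148R against parental cells. The median there went from 0.14 to -0.11. Of 23 glycolysis and lactate export genes, 8 were higher and 12 lower, 7 higher and 12 lower, and 4 higher and 11 lower (camera adjusted p = 0.18, 0.21 and 0.26), with LDHA at 1230, 900 and 553 CPM. Of 29 integrated stress response genes, 10 were higher and 8 lower, 18 higher and 9 lower, and 15 higher and 12 lower (camera adjusted p = 0.52, 0.21 and 0.5), with the cystine transporter SLC7A11 at 1.07, 4.32 and 79.3 CPM. Of 27 heat shock and unfolded protein response genes, 12 were higher and 5 lower, 17 higher and 6 lower, and 15 higher and 8 lower (camera adjusted p = 0.14, 0.061 and 0.4).

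Lists for other cell types held few tested members. Of 8 B cell markers, IGLL1 was at 67.4 CPM in parental, 2.28 in K148Q and 1.38 in K148R cells, with 2 members higher and 5 lower, 3 higher and 5 lower, and 2 higher and 3 lower (camera adjusted p = 0.16, 0.5 and 0.93). The 3 tested T and NK cell markers, without a list test, were CD4, which monocytes also express, at 226, 376 and 743 CPM, NKG7 at 52.3, 25.9 and 27.1 CPM, and CD7 at 1.51, 0.394 and 0.431 CPM. Of 5 erythroid and megakaryocyte markers, ITGA2B was at 7.0 CPM in parental, 0.504 in K148Q and 18.1 in K148R cells, with 0 higher and 2 lower, 1 higher and 2 lower, and 1 higher and 1 lower (camera adjusted p = 0.51, 0.91 and 0.99). Of 7 epithelial and fibroblast markers, KRT18 fell from 16.3 CPM to 0.198 in K148Q and 0.255 in K148R cells, with 0 higher and 2 lower, 5 higher and 2 lower, and 6 higher and 0 lower (camera adjusted p = 0.12, 0.55 and 0.05). The median of this last list was -4.65 in K148Q and 6.6 between the substitutions, or -2.47 and 4.18 with members at 0 counts held at their bounds. It was called in 2 of the 9 fits that left out a library for K148Q against parental cells (adjusted p from 0.018 to 0.21) and in 6 of 9 between the substitutions (0.015 to 0.064). Adjusted over the list alone, the counts in this and the preceding paragraph were the same except for B cell markers in K148Q (2 higher, 6 lower), and, in K148R against parental cells, glycolysis (7 higher, 13 lower), the stress response (18 higher, 10 lower) and heat shock (18 higher, 7 lower). Median, mean and test direction differed in sign for stem and progenitor markers in K148Q, erythroid markers in K148Q and between the substitutions, and B cell markers between the substitutions.

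RN7SK was far higher in K148R than in the other libraries (log2 fold change 5.82 against parental and 6.54 against K148Q cells). A candidate explanation is more RNA without a poly(A) tail carried into the K148R libraries. The other 33 tested transcripts taken to be of that kind had a median log2 fold change of 2.85 in K148R against K148Q cells. They include 20 histones, whose transcripts mostly lack the tail, and gene counts do not show which carried one. Of the 33 transcripts, 27 passed the gene-wise test as higher than in both other groups, as such carry-over would give. Most were under 1 CPM in both other groups. Many of these passed the filter on low counts only through the K148R libraries, which largely sets their rise. Of those above 1 CPM in parental cells, HIST1H1C and RN7SL2 rose from parental to K148R cells and HIST1H2BH fell. RN7SL1, RPPH1, RMRP and SCARNA12 did not pass there (log2 fold changes 0.37 to 0.96). The 13 small RNAs alone had a median of 1.58 against parental cells. Against a uniform carry-over, 91 small nucleolar RNAs had a median of 0.09 in K148R against K148Q cells. The medians of the small RNAs alone and of the small nucleolar RNAs were not part of the test fixed in advance. A change in the RNAs themselves that comes with the substitution was not tested and stays open, and while it does, the histone rise cannot be read apart from that of RN7SK.

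In 9 genes a group was near silent while the others expressed the gene, among them GLB1L2 and AGK in K148Q and GTSF1, SYT2 and CD38 in K148R cells. Loss of the chromosome segment around them may be a cause. Their 34 nearest tested neighbours had a median log2 ratio of 0.09 in the near-silent group against the others, with a bootstrap interval of -0.25 to 0.35, which argues against such loss as the cause for the 9 genes as a set. For single genes it stays open, since 3 neighbours lay below -1, the lowest at -3.27 beside SYT2, -2.98 beside CYP1B1 and -1.09 beside AGK. A deletion smaller than the gene spacing, and silencing that comes with the substitution, were not tested and stay open.

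The broad difference between the genotypes may have several sources. Whole-chromosome copy number as the whole cause is argued against. The chromosome explained only 0.48%, 0.34% and 0.43% of the variance of log2 fold change in the 3 comparisons. The first and last passed the highest of 0.39% from permuted chromosome labels. That permutation takes genes as independent, so passing it does not show a part from copy number. A small part by chromosome stays open, and segments were not tested. GC content and length bias as the whole cause is argued against too. After the correction 6343 of 6758, 8421 of 9467 and 8264 of 8965 genes stayed called in the same direction. The corrected count of changed genes was at least 105.4% of the uncorrected one. That count does not measure the share of bias, since the correction can also remove spread between libraries of a group. Divergence of the cells apart from the substitution cannot be told apart from the substitution, since the titles give 1 code per substitution, and the substitution itself stays open as untested. For each comparison, 1 of the 10 splits of the 6 libraries gave as many changed genes, the real one (6460, 10174 and 8506, highest other 0 each), and 10 splits are too few for a share under 0.05.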
